A study of Mus musculus with 9 samples.

How the data were processed

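Total RNA from whole liver, in 9 samples from male mice, was hybridised to Illumina MouseRef-8 v2 expression BeadChips, a 1-colour array that reads one biotin-labelled sample per array with bead-bound probes. Per the labels' protocols the mice received a high fat diet for 7 months, the tissue was flash frozen, RNA was extracted with Trizol, cleaned on a column with DNase treatment and checked on a Bioanalyser. The labels put 5 samples in the wild type group (replicates 1 to 5) and 4 in the PEDF knockout group (replicates 2 to 5), and give the age of the mice as 7 months, the same number as the diet. The labels do not say in words that each sample is a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

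The deposited values come as a value table and a scanner table, besides a log2 version of the latter. The deposited value table holds 25697 probes for the 9 labelled samples, in log2 units relative to the probe's own median. Its scale is not described in the sources used here and was worked out by comparing, probe by probe, the sorted 9 values with the sorted 9 scanner values. For 100.0% of probes they matched log2 of the signal minus the array's 75th percentile minus the probe's median over the arrays, within 0.005, so the authors' values carry a shift of each array and a centring of each probe and no visible background correction. Without the shift 0.0% matched. The direction of the log2 scale is thereby known, and the software that made it is not given in the sources used here. The medians of the 9 columns of the value table lay between -0.22 and 0.07. The deposited scanner table gives the average bead intensity (signal) and a detection p-value per probe and array, per the file headers, and 4 of its lines hold text fragments that name no probe. Signals started at 97.1, so background had not been subtracted.

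The columns of the scanner table carry only a chip and a position, which no label ties to a sample. None was given a sample here. Of 36 such per-sample columns, 18 (signal and detection p) were used only pooled over the 9 arrays, as the mean signal and median level of a probe, the number of arrays that detect it, and the comparison of sorted values above. The other 18 columns, which belong to a log2 version of the scanner table, were not used. The pooled columns set which probes entered and the overall level of a probe. Every difference between samples comes from the sample-labelled table. The 9 arrays lay on 2 chips that hold 5 and 4 arrays, the same sizes as the 2 groups. Which samples shared a chip is not known here, so a chip could not be used as a block, and chip and genotype could coincide.

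The plan fixed before the data were examined called for the neqc method on the scanner table. That method needs scanner values per sample, so the fallback of the plan was used: log2 values and quantile normalization. The probe's median level was added back to the value table, and the 9 arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Levels are therefore log2 signals relative to the 75th percentile of an array. No background correction was made, so fold changes of dim genes are understated. A probe entered if its detection p was under 0.05 on at least 4 of the 9 arrays, which left 11708 probes. The brightest probe stood for a gene, which left 8723 genes. Genes were named through the Entrez ID in the file for 23788 probes and through the transcript accession for 1148 probes, against the GRCm38.p6 gene table, and 761 probes kept the symbol of the file. Probes on different parts of a gene can disagree: of 233 further detected probes of called genes, 29 had the opposite sign. Paralogs with near-identical transcripts, such as the Cyp2b, Gsta and Serpina families, may share signal.

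Knockout was compared with wild type in 1 limma fit (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over the 8723 genes and a threshold of 0.05. Standard errors are those of the moderated fit. Of 37 gene lists fixed before the data were examined, 36 had at least 5 measured members and were tested with camera at its preset correlation between genes of 0.01, adjusted over the 36 lists. One list, of muscle markers, had too few. Camera with an estimated correlation and fry were alternatives. A score per array, the mean over a list's members of the log2 value relative to the gene's mean, was compared with an exact two-sided permutation test over the 126 splits of 9 arrays into 5 and 4, for which the smallest p is 0.0159. The lists cover Wnt feedback targets and components, pericentral and periportal hepatocyte genes, lipid, sterol, bile acid, glucose and drug metabolism, sex-biased liver genes, fibrosis and cell type markers, immune and stress responses, proliferation, oncofetal genes, clock, ribosomal and respiratory chain genes, genes near Serpinf1, strain markers and genes tied to PEDF.

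Genes named in the text follow a rule fixed in advance. It takes Serpinf1; Glul, Axin2, Lgr5, Cyp2e1, Cyp1a2, Tbx3, Ccnd1, Myc, Lrp6 and Ctnnb1 whatever their result; the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap; and up to 4 members with the smallest p from each list past the threshold and from 7 further lists fixed by name. A few genes that the rule takes are not reported, and were not replaced. Other genes are named as members of a count or tested set, or for the size of their difference. Those picked out of a list or for their size were chosen by their values.

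The steps were tested on simulated data for the comparison of knockout with wild type: 10 simulations of 8723 genes with the measured means and spreads, each with 200 changed genes. The fit called 74.9% of genes changed by 0.5 on the log2 scale, 97.8% of those changed by 1 and 99.4% of those changed by 2, with 5.2% false calls among all calls, and camera called 0 lists. The simulated genes were independent, which real genes are not. The simulated arrays were independent too, without near-alike knockouts or a chip effect, so these rates need not hold for the real arrays.

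Alternatives tried were median scaling, the deposited scaling, no detection filter, the mean of detected probes, trend and robust variance, array weights, the replicate number as a block, leaving out each array in turn, the other list tests, and, added after the data were seen, normexp background correction, a stricter detection filter, 3 arrays against 3, median scaling together with an estimated correlation, and knockout 2 and 3 averaged as 1 replicate. The precision is limited by the number of arrays. Between 10754 and 12211 probes were detected per array, and array medians lay between 136.9 and 162.9 signal units, against a median of 129.5 over the 9963 probes detected on 0 of the 9 arrays.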

Results

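Gene expression was measured in livers of male mice kept on a high fat diet for 7 months, in 5 wild type samples and 4 samples from mice that lack pigment epithelium-derived factor (PEDF), a secreted glycoprotein of the serpin family encoded by Serpinf1. The series asks about Wnt/beta-catenin signalling in the liver, and its design holds 1 comparison, knockout against wild type. Of 25697 probes, 11708 were detected on at least 4 arrays and gave 8723 genes. Levels are log2 signals relative to the 75th percentile of an array, and differences are knockout minus wild type.

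Serpinf1 signal was far lower in the knockout samples. The 5 wild type arrays read 6.26, 6.52, 6.26, 6.36 and 6.70, and knockout arrays 2 to 5 read -0.68, -0.67, -0.80 and -0.88. The difference was -7.17 ± 0.10 (SE, n = 5 and 4; limma adjusted p = 5.74e-14), or 144-fold. The single probe lies on chromosome 11 at 75223538 to 75223587 as the array annotation gives it, with a build that is not given in the sources used here. Whether it lies in the deleted part of the gene is not stated in the labels. The probe was detected on 8 of the 9 arrays, so at least 3 knockout arrays still read it above background at the detection threshold. The lack of background correction understates the fold.

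The knockout livers showed 377 genes with higher and 289 with lower signal at an adjusted p under 0.05 (limma). Among these, 26 rose and 22 fell by more than 1 on the log2 scale. In 318 of the higher and 224 of the lower genes the 4 knockout arrays lay beyond the 5 wild type arrays. Over all genes 10.8% had such separated groups, against 1.6% expected by chance if the arrays are independent samples. That is in doubt for knockouts 2 and 3, and the expected share is higher if both are 1 sample. The balance of directions depends on the scaling: 364 higher and 607 lower genes were called with median scaling, and 325 higher and 659 lower with the deposited scaling. Before quantile normalization the SD of levels was lower on each knockout array (1.52 to 1.55) than on any wild type array (1.56 to 1.70). The first principal component held 46.3% of the variance and separated the genotypes, at -14.94 to -7.59 for wild type and 13.33 to 22.28 for knockouts 2 to 4, with knockout 5 at 2.42.

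The 4 knockout arrays were not equally independent. Knockouts 2 and 3 differed by at most 0.62 in any gene other than Serpinf1 (log2), while the largest difference in each of the other 15 pairs of arrays within a group was 1.43 to 4.18. With these arrays averaged as 1 replicate (n = 5 and 3), 146 genes were higher and 94 lower. Leaving out knockout 2 gave 164 and 104 genes, knockout 3 gave 120 and 86, knockout 4 gave 162 and 103, knockout 5 gave 540 and 464, and wild type 5 gave 246 and 176, in the order higher and lower. Without knockout 5, wild type 1 and wild type 2, which stood apart on the principal components, 848 and 740 genes were called. Arrays chosen for lying apart from their group leave a smaller spread by construction, so calls gained with these 3 arrays against 3 are left out of the counts of alternatives passed. The 2 chips held 5 and 4 arrays, and no scanner column was tied to a sample here, by label or by its values. Whether chip and genotype coincide is therefore not known here, and an effect of the chip was not separated from genotype.

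Among called genes whose groups did not overlap, the largest rise was in Cyp2b9, a cytochrome P450. Cyp2b9 rose by 2.92 ± 0.49 (SE, n = 5 and 4; adjusted p = 0.00705), Cyp2b23 by 2.15 ± 0.33 and Cyp2b13 by 2.02 ± 0.32. Ly6d, a surface protein, rose by 2.06 ± 0.29 (adjusted p = 0.00459). Lcn2, an iron-siderophore binding protein, rose by 1.82 ± 0.28 (adjusted p = 0.00591), and Orm2, an acute phase protein, by 1.46 ± 0.24. Anxa2, a calcium-dependent membrane-binding protein, rose by 1.72 ± 0.25 and S100a11 by 1.49 ± 0.28. Tubb2b, a beta tubulin, rose by 1.87 ± 0.25 on its brighter probe, while its other detected probe differed by -0.28, which left 0.80 with the mean of probes. Me1, the cytosolic malic enzyme, rose by 1.58 ± 0.28, Cidec, a lipid droplet protein, by 1.51 ± 0.29, and Bcl6, a transcriptional repressor, by 1.48 ± 0.21. Gsta1 and Gsta2, whose groups overlapped, also rose by over 2 (2.42 and 2.08).

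Among called genes whose groups did not overlap, the largest fall after Serpinf1 was in Serpina1e. Serpina1e, an alpha-1-antitrypsin gene, fell by 2.97 ± 0.58 (SE, n = 5 and 4; adjusted p = 0.0125), with a spread among knockouts of 1.71 (SD). Serpina4-ps1 fell by 1.82 ± 0.30. Hsd3b5, whose groups overlapped, fell by 2.38. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, fell by 1.81 ± 0.09 and had the smallest adjusted p after Serpinf1 (1.87e-07). C6, a terminal complement component, fell by 1.44 ± 0.23, Egfr, the epidermal growth factor receptor, by 1.20 ± 0.18, and the amino acid transporter gene Slc38a2 by 1.09 ± 0.18 (by 0.70 with the mean of probes). Serpina1e missed the threshold with trend and robust variance (adjusted p = 0.0593). Fam25c fell by 1.06 ± 0.21, Nnmt by 1.51 ± 0.42, Sds, a serine dehydratase, by 1.08 ± 0.30, Clca1 by 1.33 ± 0.32 and Zg16 by 1.14 ± 0.30. The last 5 missed the threshold with knockouts 2 and 3 averaged (adjusted p = 0.0509, 0.0782, 0.142, 0.0794 and 0.103). Leaving out 1 array also ended the call of Fam25c (knockout 3), Nnmt (wild type 2, 4 or 5, or knockout 2, 3 or 4), Sds (wild type 1 or 5, or knockout 2, 3 or 4), Clca1 (wild type 5, or knockout 2, 3 or 4) and Zg16 (wild type 1, 3 or 5, or any knockout), with adjusted p from 0.0504 to 0.138.

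**Figure D1:**
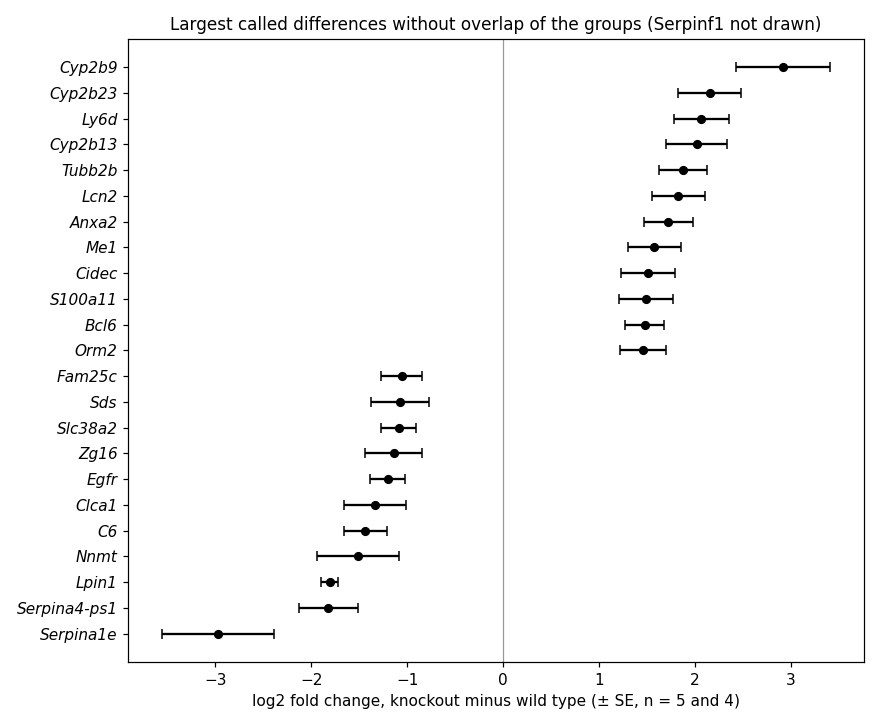
Log2 fold changes (knockout minus wild type, horizontal axis) of the called genes with the largest rises and falls whose groups do not overlap, with Serpinf1 left out for scale. Points are fitted differences and bars are ± 1 SE (n = 5 and 4), from -2.97 for Serpina1e to 2.92 for Cyp2b9.

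Of 16 measured members of the list of Wnt/beta-catenin feedback targets, 3 rose and 0 fell: Ccnd1, which encodes cyclin D1, by 0.86 ± 0.21 (SE, n = 5 and 4; adjusted p = 0.0294), Tnfrsf19 by 0.35 and Ephb2 by 0.42. The counts adjusted over the list alone were the same, 3 and 0. Axin2, a feedback inhibitor, differed by 0.02 ± 0.15 (adjusted p = 0.952) and Lgr5, an R-spondin receptor, by -0.03 ± 0.12 (adjusted p = 0.892), and Tbx3 by 0.19 ± 0.18 (-0.10 to 0.29 over the alternatives). Axin2 and Lgr5 had pooled signals of 219 and 189, near the background of 129.5, so a difference in either could be understated. The list had a median of 0.03 and a camera adjusted p of 0.107 (0.341 with an estimated correlation). It passed with median scaling (median 0.14, adjusted p = 0.00658) and with the deposited scaling (median 0.13, adjusted p = 0.00516), and under median scaling with an estimated correlation the adjusted p was 0.355. The Ccnd1 call was lost without knockout 2, 3 or 4 (adjusted p = 0.0774, 0.0655 and 0.0926) with knockouts 2 and 3 averaged (0.0732), without the detection filter (0.0572) and with trend and robust variance (0.0539).

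Among 27 measured Wnt ligands, receptors, inhibitors and cytoplasmic components, 0 rose and 1 fell, Tle1, a transcriptional corepressor, by 0.76. The list median was 0.01 (-0.02 to 0.07 over the alternatives), its mean -0.04 and its camera direction down (adjusted p = 0.611). Ctnnb1, which encodes beta-catenin, differed by 0.24 ± 0.08 (SE, n = 5 and 4; adjusted p = 0.0759), with the 4 knockout arrays above the 5 wild type arrays. The Ctnnb1 value was 0.09 with median scaling, 0.07 with the deposited scaling and 0.14 with the mean of probes, and it passed with array weights (adjusted p = 0.0307) and without wild type 2 (0.0469). The co-receptor gene Lrp6 differed by -0.15 ± 0.12 (adjusted p = 0.491; -0.26 to -0.07 over the alternatives), at a pooled signal of 197, near background. Myc was not among the genes tested.

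**Figure D2:**
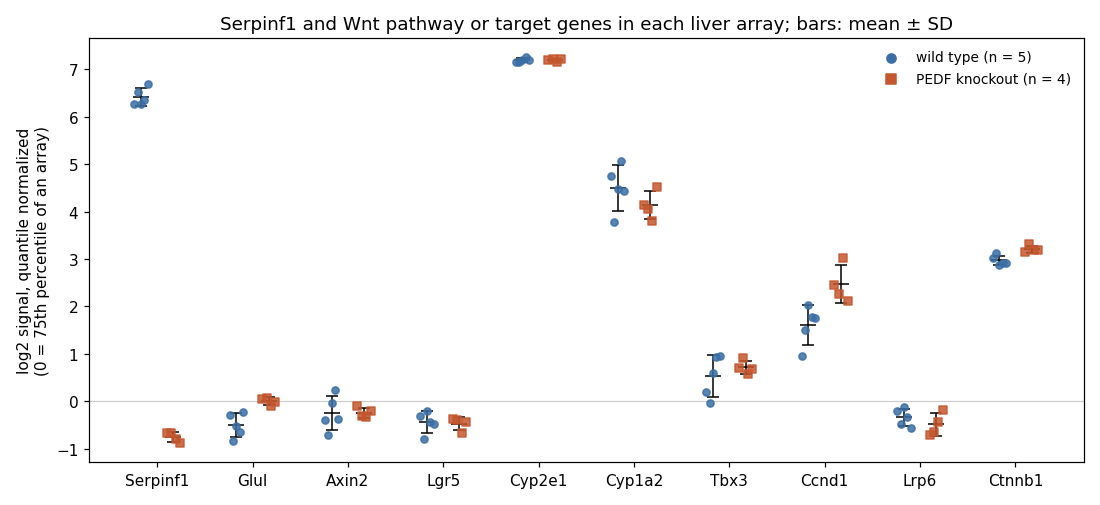
Quantile normalized log2 signal (vertical axis, relative to the 75th percentile of an array) of Serpinf1 and Wnt pathway or target genes in each array. Circles are wild type (n = 5), squares knockout (n = 4), bars mean ± SD. Serpinf1 lies between 6.26 and 6.70 in wild type and between -0.88 and -0.67 in knockout, and Axin2 and Cyp2e1 overlap between the groups.

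Pericentral hepatocyte genes, which depend on beta-catenin in liver, moved both ways. Of 30 measured members, 6 rose and 2 fell, or 8 and 3 adjusted over the list alone. Glul, glutamine synthetase, rose by 0.51 ± 0.12 (SE, n = 5 and 4; adjusted p = 0.0211), and Cyp3a11, Cyp2c29, Aldh1a1, Slc13a3 and Tnfrsf19 rose by 0.35 to 0.86. The Glul probe was detected on 8 of the 9 arrays at a pooled signal of 214, near the background of 129.5, so its fold is uncertain. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.02 and Oat by 0.45. Cyp2e1 differed by 0.01 ± 0.07 (adjusted p = 0.962), but its signal lay near the top of the scale, where quantile normalization fixes the levels, and it differed by 0.20 and 0.18 with median and deposited scaling. Cyp1a2 differed by -0.37 ± 0.21 (adjusted p = 0.308), and by -0.55 and -0.57 with those scalings, which did not pass. The list median was 0.01 (camera adjusted p = 0.4, or 0.83 with an estimated correlation), and the test turned downward without wild type 2 (median -0.06). The Glul call was lost without knockout 2 or 3 (adjusted p = 0.068 and 0.0744) and with both averaged (0.07). Of 32 periportal genes, 2 rose and 3 fell (7 and 6 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.556, or 0.843 with an estimated correlation). This list passed, downward, with median scaling (-0.26, adjusted p = 0.0402) and with the deposited scaling (-0.28, adjusted p = 0.0484).

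In the list of CAR, PXR and drug metabolism genes, 16 of 39 members rose and 2 fell (19 and 2 adjusted over the list alone; median 0.33; camera adjusted p = 1.52e-06, or 0.185 with an estimated correlation). The list median was 0.215 with the deposited scaling. Cyp2b9, Cyp2b13 and, by 0.77 ± 0.12 (SE, n = 5 and 4), Aldh1a7 were among the rises, and Por, the reductase that supplies cytochromes P450 with electrons, fell by 0.87 ± 0.13 (adjusted p = 0.00591). Cyp2b10 differed by 0.49, and Nr1i3 and Nr1i2, which encode CAR and PXR, by -0.03 and -0.19, and none of these passed. Cyp2b9 and Cyp2b13 are also members of the female-biased list. Of 30 NRF2 and oxidative stress genes, 11 rose and 0 fell (14 and 2 adjusted over the list alone; median 0.32; camera adjusted p = 2.64e-06, or 0.185 with an estimated correlation). Gsta1, a glutathione transferase whose probe may also read close paralogs, rose by 2.42 ± 0.43, Cbr3 by 1.02 ± 0.17 and Srxn1, sulfiredoxin, by 0.90 ± 0.14. Gsta1, Gsta2, Gsta4, Gstm1, Gstm2 and Ephx1 are counted as rises in both this list and the drug metabolism list, so the lists are not independent. Another detected Gstm1 probe differed by -0.008. The drug metabolism score of knockout 5 was 0.07, against 0.30 to 0.34 in knockouts 2 to 4 and -0.23 to -0.12 in wild type.

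Liver genes with a known sex difference were compared in these male mice. Of 15 female-biased genes 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.42; camera adjusted p = 1.64e-06, or 0.185 with an estimated correlation), among them Cyp2b9, Cyp2b13, Vldlr by 0.80 ± 0.11 (SE, n = 5 and 4) and Ntrk2 by 0.75 ± 0.13. Of 25 male-biased genes 2 rose and 9 fell (2 and 11 adjusted over the list alone; median -0.40; camera adjusted p = 9.98e-05, or 0.319 with an estimated correlation), with C6, Egfr and Selenbp2 (by 0.98 ± 0.17) falling and Bcl6 and Spp1 rising. Cyp2d9, Cyp4a12a, Mup1, Mup2 and Mup3 differed by -0.22 to 0.12, Cyp4a12b by -1.17 and Mup4 by -0.98, and none of these passed. Without the detection filter the medians were 0.15 and -0.12. The female-biased median was 0.27 with median and 0.26 with deposited scaling, and the male-biased median was -0.60 without knockout 5. Knockout 5 had a female-biased score of -0.01, against 0.48 to 0.55 in the other knockouts and -0.44 to -0.19 in wild type, and its male-biased score of 0.23 lay within the wild type range of 0.07 to 0.44.

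Lipid genes moved in both directions. Of 38 fatty acid oxidation and PPARalpha target genes, 8 rose and 1 fell (14 and 2 adjusted over the list alone; median 0.22; camera adjusted p = 0.000768, or 0.385 with an estimated correlation). Pdk4, an inhibitor of pyruvate dehydrogenase, rose by 0.94 ± 0.16 (SE, n = 5 and 4), and Cyp4a31 by 0.73 ± 0.13, while Angptl4, a lipoprotein lipase inhibitor, fell by 0.70 ± 0.11. Of 19 lipid droplet genes, 4 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.36; camera adjusted p = 0.00664, or 0.319 with an estimated correlation): Cidec, Vldlr, Plin3 and Lpl rose, and Plin5 fell by 0.58 ± 0.11. Of 22 cholesterol synthesis genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.22; camera adjusted p = 0.00501, or 0.529 with an estimated correlation), among them Insig2 by 0.96 ± 0.19. Sqle differed by 1.01 ± 0.31 (adjusted p = 0.0619) and Idi1 by 0.40 ± 0.12 (adjusted p = 0.053). They passed in 5 and 4 of 19 alternatives, both with median scaling (0.0481 and 0.0362), and Sqle without wild type 1 (0.0496) or 2 (0.0396).

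The calls of these lists depend on the scaling. The fatty acid oxidation and cholesterol synthesis medians were 0.11 and 0.09 with median scaling and 0.09 and 0.075 with the deposited scaling. The former was 0.135 with the mean of probes and the latter 0.136 with array weights. With median scaling the adjusted p was 0.118 for fatty acid oxidation, 0.0588 for lipid droplet and 0.0895 for cholesterol synthesis genes, and with the deposited scaling 0.106, 0.0509 and 0.078. Cholesterol synthesis also missed the threshold without wild type 1 (median 0.04, adjusted p = 0.275), whose score of -0.64 was the lowest, and with 3 arrays against 3 (0.67). Insig2 missed the threshold without knockout 3 (0.053). Plin3 missed it with median (0.0843) and deposited (0.106) scaling, with knockouts 2 and 3 averaged (0.0597), and without wild type 3 or 4 or knockout 3 or 4 (0.0541 to 0.0961). Of 25 lipogenesis genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.09; camera adjusted p = 0.0919, or 0.677 with an estimated correlation), and the list passed without wild type 3 (0.00836), wild type 5 (median 0.17, 0.0379) or knockout 5 (0.15, 0.0327). Its median was 0.15 with median scaling, which did not pass, and ran from 0.04 to 0.17 over the alternatives. Me1 and Elovl5, a fatty acid elongase (0.78 ± 0.14, SE, n = 5 and 4), rose, and Lpin1 and Mlxipl, which encodes the carbohydrate response element binding protein, fell, the latter by 0.60 ± 0.13 (adjusted p = 0.0552 without knockout 4).

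Of 38 macrophage and monocyte markers, 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.31; camera adjusted p = 3.52e-07, or 0.341 with an estimated correlation). Lgals3, galectin 3, rose by 1.23 ± 0.22 (SE, n = 5 and 4), Tlr2 by 0.63 ± 0.11, Il1b by 0.45 ± 0.08 and Mmp12 by 0.50 ± 0.11. Of 39 stellate cell and extracellular matrix genes, 11 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.19; camera adjusted p = 7.01e-07, or 0.319 with an estimated correlation), with Col6a1 at 0.76 ± 0.15, Tgfbr2 at 0.73 ± 0.14, Col1a1 at 0.66 ± 0.11 and Col3a1 at 0.48 ± 0.10. Acta2, Des, Lrat, Ngfr and Tgfb1 of the same list differed by -0.028 to 0.095 and Ccn2 by -0.41, and none of these passed. Col1a1, Col3a1 and Mmp12 were detected on 4 of the 9 arrays. The call was lost for Col3a1 without knockout 3 (adjusted p = 0.0615), and for Mmp12 without knockout 2 (0.0548), without knockout 3 (0.053) and with both averaged (0.0545). The macrophage score did not separate the groups per array: wild types 1 and 2 had 0.04 and 0.20, knockout 5 had -0.06, and the exact permutation p was 0.111. The fibrosis score overlapped between the groups too, with wild type 2 at 0.061 and knockout 5 at -0.045. So did the interferon, MHC class II, lipid droplet, fatty acid oxidation, cholesterol synthesis, male-biased and ribosomal scores.

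Of 38 interferon-stimulated genes 5 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.23; camera adjusted p = 4.14e-06, or 0.319 with an estimated correlation), including Usp18 by 0.76 ± 0.16, Lgals3bp by 0.79 ± 0.17, Ifit3 by 0.69 ± 0.14 and Cxcl10 by 0.51 ± 0.13 (SE, n = 5 and 4). Of 9 genes in the MHC class II list 2 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.54; camera adjusted p = 1.43e-05, or 0.319 with an estimated correlation), H2-Ab1 by 1.20 ± 0.27 and H2-DMb1 by 0.54 ± 0.13. This list also holds Cd83, Cd86 and Ctss, which are not MHC class II genes. H2-Aa differed by 0.93 ± 0.28 (adjusted p = 0.0599) and Cd74 by 0.95 ± 0.29 (adjusted p = 0.066), and passed in 7 and 6 of 19 alternatives, among them without wild type 1, wild type 2 or knockout 5 (0.0226 to 0.0416). With knockouts 2 and 3 averaged, Ifit3, Lgals3bp, Cxcl10, H2-Ab1 and H2-DMb1 missed the threshold (adjusted p = 0.0525, 0.0592, 0.0927, 0.0545 and 0.0664). Single arrays also ended calls: knockout 3 for Ifit3 and Usp18, knockout 2, 3 or 4 for Lgals3bp, knockout 3 or 4 for H2-Ab1, and wild type 3, 4 or 5 or knockout 2, 3 or 4 for Cxcl10 and H2-DMb1 (adjusted p from 0.0503 to 0.105). The calls were also lost for Ifit3 with the mean of probes (0.42, adjusted p = 0.0693), for H2-Ab1 with trend and robust variance (0.0643) and for Cxcl10 without the detection filter (0.0509). Without that filter the median was 0.12 for the interferon, 0.34 for the MHC class II and 0.04 for the neutrophil list. Of 5 neutrophil genes 1 rose, Lcn2, and 0 fell (2 and 0 adjusted over the list alone; median 0.31; camera adjusted p = 0.0102, or 0.295 with an estimated correlation). S100a8, S100a9 and Fpr2 differed by 0.46, 0.13 and 0.31 and did not pass, with S100a9 at 0.055 to 0.27 over the alternatives. S100a8 passed without wild type 2 (adjusted p = 0.0212), without knockout 5 (0.0467) and with array weights. Lymphocyte, endothelial and blood cell lists had adjusted p of 0.745, 0.745 and 0.964.

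Of 27 proliferation genes 10 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.27; camera adjusted p = 2.64e-06, or 0.319 with an estimated correlation): the replication helicase genes Mcm4 and Mcm6 rose by 0.58 ± 0.12 and 0.56 ± 0.12, and Cdkn1a, a cyclin-dependent kinase inhibitor that restrains the cycle, by 0.58 ± 0.12 (SE, n = 5 and 4). Tk1, thymidine kinase, fell by 0.82 ± 0.10 (adjusted p = 0.00372). Of 17 oncofetal and liver tumour markers 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.30; camera adjusted p = 1.64e-06, or 0.295 with an estimated correlation), among them Ly6d, Anxa2, S100a11, Cbr3 and Anxa5, the last by 0.91 ± 0.16. Golm1, Spink1, Gpc3 and Igf2 of this list differed by 0.24, 0.19, 0.17 and -0.06 and did not pass. Among its called members, Cbr3 is also in the NRF2 list and Mcm6 in the proliferation list. Without the detection filter the median was 0.10 for proliferation and 0.04 for oncofetal genes, and the oncofetal median was 0.19 without knockout 4 and 0.50 without knockout 5. With the mean of probes Tk1 fell by 0.49 and Cdkn1a rose by 0.36. Knockout 4 had the highest scores, 0.37 for proliferation and 0.73 for oncofetal genes, and knockout 5 the lowest of the knockouts, 0.04 and 0.03.

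Of 19 clock genes and outputs 2 rose and 5 fell (2 and 9 adjusted over the list alone; median -0.17; camera adjusted p = 0.00264, or 0.185 with an estimated correlation). Tef fell by 0.76 ± 0.12, Por by 0.87 and Alas1, the first enzyme of heme synthesis, by 0.52 ± 0.10, while Nampt rose by 0.58 ± 0.10 (SE, n = 5 and 4). Of 25 immediate early and heat shock genes, which handling of tissue can move, 7 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.11; camera adjusted p = 0.00987, or 0.185 with an estimated correlation). Egr1 rose by 1.07 ± 0.11 (adjusted p = 0.00121), Fos by 0.49 ± 0.08 and Gadd45a by 0.69 ± 0.12, and Fkbp5, a glucocorticoid-induced gene, fell by 0.78 ± 0.12. Of 55 ribosomal protein genes 0 rose and 6 fell (1 and 9 adjusted over the list alone; median -0.10; camera adjusted p = 0.00234, or 0.295 with an estimated correlation), among them Rpl34 by 0.41 ± 0.08 and Rps10 by 0.47 ± 0.10. Alas1 and Rps10 missed the threshold with knockouts 2 and 3 averaged (0.0506 and 0.0594), Alas1 and Rpl34 without knockout 3 (0.053 and 0.0525), and Rps10 without knockout 2, 3 or 4 (0.0604, 0.0608 and 0.0576). With median and deposited scaling the median was -0.21 and -0.23 for ribosomal and -0.26 and -0.28 for clock genes. Without the detection filter it was -0.09 for clock and 0.05 for immediate early genes, and the latter was 0.16 without wild type 1 and 0.19 without wild type 2. With the mean of probes Tef fell by 0.41.

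Of 5 measured pancreas markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.0413, or 0.319 with an estimated correlation), Zg16 and Cela1, an elastase (by 1.09 ± 0.29, SE, n = 5 and 4). Ins1, Cela2a and Ctrl differed by -0.10, -0.07 and -0.03 and did not pass (list median -0.10), and the signs of Ins1 and Cela2a turned with median and with deposited scaling. Ins1 and Cela2a had pooled signals of 150 and 151, near the background of 129.5. Scores in wild type ranged from -0.14 to 0.54. With median scaling the list median was 0.04 and the adjusted p 0.451, with the deposited scaling 0.03 and 0.473. The adjusted p was 0.579 without the detection filter and 0.054 with knockouts 2 and 3 averaged. It also missed the threshold without wild type 1, wild type 3, knockout 3 or knockout 5 (adjusted p = 0.0884, 0.0513, 0.0721 and 0.0573). Cela1 missed it with knockouts 2 and 3 averaged (0.11) and without wild type 3, 4 or 5 or knockout 2, 3 or 4 (0.0791 to 0.127).

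The remaining lists did not pass with camera: adipocyte (median 0.51, adjusted p = 0.0635), cholangiocyte (0.11, 0.0635), respiratory chain (0.07, 0.0765; the direction turned with median and deposited scaling), glucose and insulin response (-0.10, 0.342), PEDF-related genes (0.03, 0.422), acute phase (0.02, 0.799), endoplasmic reticulum stress (0.04, 0.745) and bile acid genes (-0.04, 0.872). Over the alternatives the median ran from 0.025 without the detection filter to 0.665 without wild type 3 for adipocyte, from 0.02 to 0.27 for cholangiocyte and from -0.10 to 0.09 for respiratory chain genes. It ran from -0.03 to -0.21, the latter with the deposited scaling, for glucose and insulin response, from -0.015 to 0.07 for PEDF-related, from -0.13 to 0.10 for acute phase, from -0.07 to 0.05 for endoplasmic reticulum stress and from -0.08 to 0.035 for bile acid genes. The adipocyte list passed upward in 9 of 22 alternatives, among them median (0.0248) and deposited (0.024) scaling, fry (0.00654), and leaving out wild type 3 (0.0479), knockout 4 (0.0345) or knockout 5 (0.0428). The cholangiocyte list passed in 6, among them leaving out wild type 3 (0.0444), wild type 5 (0.0417) or knockout 5 (0.0135), and the respiratory chain list with array weights (0.0385). Strain markers had a median of -0.05 (-0.09 to 0.08 over the alternatives), a mean of 0.12 and an upward test (adjusted p = 0.395, or 0.0314 with fry), with Ide (0.47) and Gsta4 (0.57) called higher and 0 of 7 members lower. Among the 18 lists past the threshold with the preset correlation, 0 passed with an estimated correlation (lowest adjusted p = 0.185). With fry, which tests a list's genes alone, 10 of these 18 passed, as did the adipocyte and strain marker lists. Those that missed were the lipid droplet, fatty acid oxidation, cholesterol synthesis, male-biased, fibrosis, macrophage, interferon and MHC class II lists. Their adjusted p with fry was 0.061 to 0.29. In the exact permutation test on scores 0 of 36 lists passed (lowest adjusted p = 0.0544), and 17 of the 18 lists passed with knockouts 2 and 3 averaged. The median and mean differed in sign for endoplasmic reticulum stress (mean -0.004, test upward) and blood cell genes (mean -0.01, test downward).

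**Figure D3:**
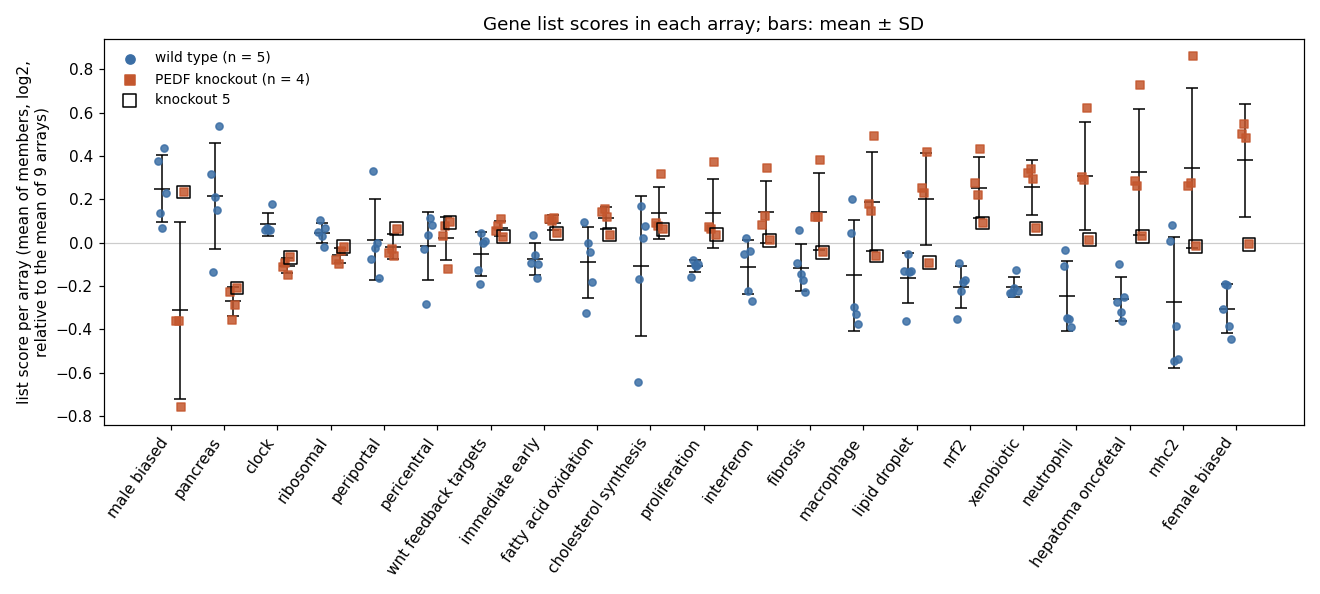
Score of each gene list per array (vertical axis: mean over members of the log2 signal relative to the gene's mean over 9 arrays) for the lists past the camera threshold and the Wnt feedback, pericentral and periportal lists. Circles are wild type (n = 5), squares knockout (n = 4), bars mean ± SD, and an open black square marks knockout 5. Its female-biased score is -0.01, against 0.48 to 0.55 in the other knockouts.

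Genes beside Serpinf1 on chromosome 11, where donor-strain sequence can remain in a knockout line, gave 1 call among 23 measured (2 adjusted over the list alone; list camera adjusted p = 0.743, or 0.772 with an estimated correlation). Rtn4rl1, a neuronal membrane receptor gene of this region, rose by 0.65 ± 0.07 (SE, n = 5 and 4; adjusted p = 0.00121), to levels above wild type on 4 of 4 knockout arrays. Ovca2, Serpinf2 and Inpp5k differed by 0.25, -0.33 and -0.20 (adjusted p = 0.0511, 0.0659 and 0.133). Serpinf2 passed in 7 of 19 alternatives, among them median (-0.49, 0.0169) and deposited (-0.51, 0.0169) scaling and leaving out wild type 1 (0.0375) or knockout 5 (0.032), and Ovca2 passed in 3.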

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

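The tests on Serpinf1 in knockout 5, on the likeness of knockouts 2 and 3, the averaging of both and the fit of all other splits were chosen after the results they concern were seen. A sample far from the others of its group was found for 14 of 256 sets of values (each named gene and list score in each genotype), where chance gives about 1 in 20. Values in parentheses are the gap to the nearest array divided by the range of the group.

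Knockout 5 was the sample set apart in 6 of these 14. It was lowest for Bcl6 (0.848) and Elovl5 (0.838) and highest for Serpina4-ps1 (0.94), and it had the lowest scores for xenobiotic (0.842), female-biased (0.886) and adipocyte (0.89) genes. Wild type 2 was highest for Sds (0.77) and lowest for the lipid droplet score (0.74). Knockout 4 had the highest cholesterol synthesis (0.888) and proliferation (0.899) scores. Wild type 1 was highest for Rtn4rl1 (0.766), knockout 3 lowest for Ins1 (0.83), wild type 4 highest for the xenobiotic score (0.761) and wild type 5 highest for the clock score (0.895).

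Knockout 5 lay nearer to wild type than knockouts 2 to 4. A wild type sample under a knockout label, or wild type RNA mixed in, is argued against by Serpinf1, which was -0.171 (log2) relative to the mean of the other knockouts. Compressed signal on that array as what sets it apart from the other knockouts is argued against by its SD of levels, 1.547, which ranked 2 from the lowest of 9 and lay within the range of the other knockouts (1.52 to 1.554). All 4 knockout arrays had a lower SD than the 5 wild type arrays (1.557 to 1.699), and whether that narrower range comes with genotype or chip is not known here. Over 593 genes called with knockouts 2 to 4 against wild types 1 to 3, the difference of knockout 5 from wild types 4 and 5 had the same sign in 83.3% and a median ratio of 0.38, which is consistent with a weaker form of the same difference, although choosing genes by their size in other arrays can lower such a ratio, and the same calculation for knockouts 2, 3 and 4 gave 1.01, 0.768 and 1.16 over only 1, 4 and 22 genes. Differences between animals and an effect of the chip stay open.

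Knockouts 2 and 3 were nearly alike, with an SD of differences of 0.151 against 0.197 to 0.308 in the other 15 pairs within a group. A single scan deposited under both names is argued against, since 23 of 25697 probes held exactly equal values and 797 lay within 0.005 (log2). Where RNA differs, separate probes of a gene should move together: over 677 genes with a pair of bright probes the correlation across genes of the difference was 0.208, the lowest of 36 pairs of arrays (0.27 to 0.749 in the other pairs within a group) and above chance (permutation p = 1e-04, the smallest that 10000 permutations can give). Genes are not independent replicates. That 1 RNA sample was labelled and measured on 2 arrays therefore cannot be told apart from 2 very similar animals, because separate labelling could also move the probes of a gene together.

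The shift of sex-biased genes was tested against 3 explanations. Female mice among the knockouts are argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose lowest mean on a knockout array was -0.107 relative to wild type. Cross-hybridisation among Cyp2b paralogs does not account for the whole list, since its median without Cyp2b genes was 0.283 with 5 of 13 members higher past the threshold. Lower growth hormone signalling is a candidate explanation: the median of Socs2, Cish, Igfals and Ghr was -0.733, with Socs2 past the threshold (-1.03 ± 0.22 SE, adjusted p = 0.015), Cish, Igfals and Ghr not (adjusted p = 0.0826, 0.0752 and 0.115), and Igf1, outside the tested set, lower as well (-0.39, adjusted p = 0.0469). The male-biased genes did not move as 1 group: 9 of 25 fell, while Cyp2d9, Cyp4a12a, Mup1, Mup2 and Mup3 differed by -0.22 to 0.12 and did not pass. Knockout 5 had a female-biased score of -0.01, above the highest wild type (-0.19) and below the other knockouts, and a male-biased score within the wild type range, and growth hormone itself was not measured.

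Of 100 splits of the 9 arrays into 5 and 4, drawn with the real one among them, 1, the real one, gave as many higher genes (377, highest other 79) and 1 gave as many lower genes (289, highest other 76). Chance is thus unlikely to give either count, if the 9 arrays are separate samples. Whether knockouts 2 and 3 are separate is not settled, and with both averaged 146 genes were higher and 94 lower. The splits treat both as separate, so they do not exclude chance for that case. Since the highest other count rests on which splits are drawn, all 125 other splits were also fitted, and their highest counts were 79 and 76 as well. An earlier draw of 99 had missed that split and gave 6 and 14. The split with 79 and 76 genes set wild types 2 to 5 against wild type 1 with the 4 knockouts, so it holds most of the genotype comparison itself.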

How the results depend on the processing

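Normexp, the stricter detection filter, 3 arrays against 3, median scaling with an estimated correlation and the averaging of knockouts 2 and 3 were chosen after the data were seen. Serpinf1 kept its direction and call under all 20 alternatives that fit genes (-7.89 to -7.10). Over named genes, 1632 results kept direction and side of the threshold, 116 lost the call, 45 gained one and 23 reversed, and over other lists 636, 62, 23 and 35. Of the gained calls, 8 and 3 came with 3 arrays against 3, where leaving out the arrays apart from their group lowers the spread by construction. A list counts as reversed where the direction of its camera test turned. The median kept its sign in such a reversal for blood (reported median 0.003) and Wnt components (0.011) throughout, for endothelial (0.022) and periportal (-0.133) genes, for bile acid genes without wild type 4 and for endoplasmic reticulum stress with 3 against 3. Dim genes lie near background, which limits their folds. Median scaling moved the 2908 dimmest of 8723 genes by 0.11 and the 2908 brightest by -0.138 (medians), and the Wnt feedback (0.092), periportal (-0.141), ribosomal (-0.145) and respiratory chain (-0.149) lists, which hold 75% dimmest and 78.1%, 85.5% and 84.4% brightest members. Averaging or leaving out arrays leaves fewer samples, and the cause of the other changes below was not tested. The planned log2 table, chip block and filter by group were not run, since no label ties those columns to samples, and the planned fit without background correction is the one reported.

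With median scaling 607 genes were lower, the Wnt feedback list gave 0.142 and the periportal list -0.26, both past the threshold, and directions reversed for Lgr5 (0.053), Ins1 (0.043), Cela2a (0.061), Wnt components (0.066), blood (0.08), endoplasmic reticulum stress (-0.053), acute phase (-0.114) and respiratory chain (-0.083) genes, the lists also with an estimated correlation. With the deposited scaling 659 genes were lower, the Wnt feedback list gave 0.127 and the periportal list -0.276, and reversals were Lgr5 (0.038), Ins1 (0.027), Cela2a (0.045), Wnt components (0.051), blood (0.064), endoplasmic reticulum stress (-0.069), acute phase (-0.13) and respiratory chain (-0.099). Without the detection filter Wnt components (0.012), lymphocyte (-0.02) and blood (0.023) reversed. Blood reversed with the probe mean (0.003) and normexp (0.01). Normexp also gave larger values for Col1a1 (1.021), Col3a1 (0.772), Mmp12 (0.802), Fos (0.742), fibrosis (0.289), neutrophil (0.468) and pancreas (-0.171) genes. Array weights called 683 higher and 594 lower genes and reversed Axin2 (-0.051) and blood (0.028). Knockouts 2 and 3 averaged gave 146 and 94. The 3 against 3 arrays gave 848 and 740, with larger medians for oncofetal (0.52), neutrophil (0.514), macrophage (0.48), fibrosis (0.304) and immediate early (0.267) genes, and reversed Axin2 (-0.186), Cyp2e1 (-0.027), Tbx3 (-0.101), pericentral (-0.089), blood (0.063) and endoplasmic reticulum stress (0.015) values.

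Same-number samples did not correlate (-0.105, 0.036, -0.082 and 0.119 for numbers 2 to 5), so the numbers are not taken to pair them. The replicate block called 410 higher and 337 lower genes and reversed Axin2 (-0.013), Lgr5 (0.004), Cyp2e1 (-0.004) and bile acid genes (0.018).

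Leaving out each array in turn gave 120 to 540 higher and 86 to 464 lower genes, and reversals within these ranges: Axin2 -0.094 to 0.141, Lgr5 -0.122 to 0.035, Cyp2e1 -0.004 to 0.023, pericentral -0.055 to 0.059, periportal -0.154 to -0.079, bile acid -0.076 to 0.02, endothelial 0.004 to 0.088, blood -0.04 to 0.079, endoplasmic reticulum stress -0.044 to 0.051 and acute phase -0.052 to 0.067.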

Other observations

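The tests of Dbp and Nr1d1 were chosen after their values were seen, as were the gene families named here. Microtubule genes were among the higher genes outside the fixed lists: Tuba1b, Tubb2b, Tubb4b and Tubb6 passed the threshold, 4 of 18 measured members of that annotation term. Acyl-CoA thioesterase genes Acot2, Acot3 and Acot4 and Baat passed as well, 4 of 10 members of their term, while another Acot2 probe differed by -0.07 and Acot1 by -0.37 (adjusted p = 0.115). These groups came from a search over 291 process terms of the array annotation in which 0 of 582 tests passed (lowest adjusted p = 0.205, Fisher's exact test against 5958 annotated genes), so neither is an enrichment beyond the search.

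Glucocorticoid-responsive and clock genes were both among the falls, such as Tsc22d3 at -0.95 ± 0.12 and Fkbp5 at -0.78 ± 0.12 (SE, n = 5 and 4). A hypothesis of lower glucocorticoid signalling at collection was tested on 8 measured response genes, of which Pdk4 had already been seen: their median was -0.255 with a camera p of 0.693, with Klf9 and Errfi1 lower and Pdk4 higher past the threshold, so the test did not settle it. A difference in the time of day at collection is also possible. Of 2 outputs with wide daily swings, Dbp had the larger shift, 0.223 in size (-0.22 ± 0.08 SE, adjusted p = 0.122), at a pooled signal of 7898 far above the background of 129.5. Nr1d1 had a pooled signal of 214, near background, so the pair cannot tell. Collection times are not given in the labels.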
